A study of Mus musculus with 20 samples.

How the data were processed

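Each of 5 stages of mouse male germ cells gave 2 m6A immunoprecipitated and 2 input libraries, in 10 groups of 2 and 20 libraries in all, per the labels. Reads were aligned to mm10 with TopHat2 2.0.14, per the submitters' processing notes. The peak caller, its threshold, the annotation version and the scaling between libraries are not given in the sources used here. The authors deposited 1 table of raw and mapped reads per library and 1 peak table per stage. Each peak has an Entrez gene, a RefSeq transcript, start and end on that transcript, a location label, and for each replicate a deposited log2 enrichment and a deposited log2 ratio of that enrichment to another stage, per the file headers. Each stage has a single list with a value per replicate, so peaks cannot be recalled without one of the replicates.

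The comparison stage behind each ratio is not named in the headers and was identified from the values. Enrichment minus ratio correlated across overlapping peaks with the enrichment of 1 other stage at r of 0.997 to 0.998, and with every other stage at 0.408 to 0.732. The deposited label of common peaks held exactly where a peak of that stage overlapped. By this, undifferentiated spermatogonia were set against type A1, type A1 against preleptotene, preleptotene against undifferentiated, pachytene/diplotene against round spermatids, and round spermatids against pachytene/diplotene. Comparison stage values were recovered as enrichment minus ratio.

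Gene symbols were updated through Entrez gene, then RefSeq accession, then synonym, with a table of the assembly GRCm38.p6, whose coordinates are those of mm10. Of 84778 peaks, 83876 matched by gene, 821 by accession and 51 by synonym, and 30 kept the deposited symbol. Deposited symbols had turned into dates at 129 peaks. Gene coordinates are from this table, positions of peaks are on the transcript, and no genome sequence was used here, so sequence motifs, transcript lengths and distances to the stop codon were not analysed here. The preleptotene table has no start or stop codon label and 4120 blank ones (22.0%). These were assigned by their place relative to coding peaks of the same transcript, which left 1095 unassigned. The same rule applied to the labelled peaks of the other tables was right for 99.0% to 99.5% of the peaks it could place.

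Depth was 9622068 to 22402907 mapped reads per library. Counts behind single peaks were not used here, so the precision of a peak's value comes only from its 2 replicates. Replicates correlated across peaks at r of 0.841 to 0.892, with an SD between replicates of 0.22 to 0.39 on the log2 scale.

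Before the data were examined, the comparisons, the 15 gene lists and the rule for named genes were fixed. The rule names, per list and stage or transition, up to 4 members with the highest enrichment and up to 2 without a peak, in alphabetical order. It adds, per transition, the 5 gained and 5 lost genes with the highest enrichment, per stage the 3 genes with most peaks and the 3 with the highest enrichment, 17 fixed genes in every stage, and the 10 genes with the highest lowest-of-5 enrichment. Some genes the rule names are not reported here. Symbols starting with Gm and a digit, ending in Rik or holding a hyphen were left out of the transition, stage and all-stage parts of the rule. Genes were counted as marked when they had at least 1 peak. Peaks overlapped when they shared at least 1 nt of a transcript (bedtools 2.31.1). Lists with at least 5 members marked in any stage, or for a transition at least 5 gained or lost, were tested with Fisher's exact test (two-sided, scipy 1.17.1) over genes marked in any stage, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals of shares are Wilson 95% intervals, and those of ratios of shares are 95% percentile bootstrap intervals (1000 draws). The draws treat both replicates of a peak and the peaks of a gene as independent values, so the bootstrap intervals may be too narrow.

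The test of single peaks was chosen after the tables were seen to hold values per replicate. Enrichments of the stage and its comparison stage, 2 against 2, were centred on each column's median and fitted with limma 3.58.1 (lmFit, eBayes, R 4.3.3), without a replicate block, with two-sided p adjusted over all peaks of the table. Peaks with a value of exactly 0 were left out, between 43 and 188 per table. Leading peaks are the 5 highest and 5 lowest differences among those called, a rule also set after the data were seen, as was the naming of the 6 X-linked genes of pachytene/diplotene. Gene lists were tested with camera and fry in 59 list and comparison combinations. With the preset correlation camera called 4, with an estimated correlation 0 (0 also at an unadjusted p under 0.05), and fry, which asks whether a list's peaks move on balance in one direction, called 14.

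Scripts were tested on simulated data. With 50 peaks changed per size, limma recovered 0% to 4% of log2 differences of 1, 68% to 84% of differences of 2, 94% to 100% of 3 and 98% to 100% of 4 over the 5 comparisons, and called 2 to 7 unchanged peaks. So few changed peaks make the adjusted threshold stricter than in the data, where 1362 to 5741 peaks were called. These shares therefore do not give the power of the tests on the data. The list test called 100 of 100 simulated lists of 50 genes with 80% marked against 46.9% of all genes in round spermatids, and 0 of 100 with 90% marked against 75.9% in undifferentiated spermatogonia. Of 100 random lists it called 1 in round spermatids and 0 in undifferentiated spermatogonia. The adjustment was over all simulated lists and stages, a larger family than the 75 real tests, so these numbers do not carry over to them. In the real family ribosomal protein genes, with 89.8% of 49 marked in undifferentiated spermatogonia, were called.

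Alternatives fixed in advance were a 4-fold minimum enrichment, the peaks above the median enrichment of each table, the same number of best peaks from every table (10950), a reciprocal overlap of 50%, autosomal peaks only, genes with at least 2 peaks, list members held by 1 list only, a background of genes marked in at least 2 stages, and leaving out replicates. Added after seeing the data were a background without the undifferentiated table, other centring and quantile normalization, kept zeros, common peaks only, the replicate number as a block, and leaving out replicates in the single-peak tests. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.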

Results

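N6-methyladenosine (m6A), the internal mRNA mark laid down by the Mettl3 and Mettl14 methyltransferase, was mapped by antibody enrichment and sequencing in mouse male germ cells of 5 successive stages. These were undifferentiated spermatogonia, type A1 spermatogonia, preleptotene spermatocytes about to enter meiosis, pachytene/diplotene spermatocytes in mid-meiosis, and haploid round spermatids. Each stage had 2 immunoprecipitated and 2 input libraries, 20 in all, with 9622068 to 22402907 mapped reads per library. The labels do not say that replicates came from separate animals, so p-values between replicates measure only the spread between these samples, which may be technical. Outside type A1, between 92.8% and 97.6% of reads mapped. The type A1 libraries stood apart, with 73.2% and 68.3% in the inputs and 87.5% and 85.5% in the immunoprecipitates. Values written as mean ± SD are log2 enrichments of the strongest peak of a gene over the 2 replicates of a stage (n = 2), as deposited. In comparisons of single peaks they are those of the peak tested, and the value of the comparison stage at that peak is the deposited enrichment minus the deposited ratio. Enrichment levels are described within a stage's table, because the tables state no common normalization.

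The 5 tables held 84778 peaks on 11972 genes. Peaks (and genes with a peak, called marked here) numbered 23031 (9088) in undifferentiated spermatogonia, 16392 (7317) in type A1, 18749 (7467) in preleptotene, 15656 (6713) in pachytene/diplotene and 10950 (5613) in round spermatids. The lowest log2 enrichment of a listed peak was 1.48, 0.71, 1.42, 1.55 and 0.61 along the 5 stages. A weak peak could thus be listed in type A1 or round spermatids and not in the other stages. Of the 11972 genes, 2894 (24.2%) were marked in all 5 stages. Leading these was Ccnyl1, a cyclin-like gene, whose lowest value was 4.85 ± 0.22 in type A1 and whose value was 7.73 ± 0.59 in pachytene/diplotene. Ppp4r2, Usp34, Nxf1, Dym, Ywhaq, the noncoding RNA Malat1, Heca and Picalm were among those that followed, with lowest values between 4.59 (Ppp4r2) and 4.08 (Picalm). These lowest values all lay in type A1 or round spermatids, the tables with the lowest median enrichments (1.76 and 1.67). The order therefore ranks genes by their values in those tables. The histone methyltransferase gene Kmt2d was among the 3 genes with most peaks in 4 stages, with 25 peaks in undifferentiated spermatogonia, 15 in type A1 and 23 each in preleptotene and pachytene/diplotene. Dst had 26 peaks in undifferentiated spermatogonia and 14 in round spermatids, and the axonemal dynein gene Dnah8 had 15 each in pachytene/diplotene and round spermatids. The most enriched peaks lay on Hmgn1 (9.50 ± 0.10), Actr3 (9.25 ± 0.62) and Ywhaq (9.11 ± 0.23) in undifferentiated spermatogonia, and on Foxn2 (5.04 ± 0.13), Taf9b (4.95 ± 0.33) and Ppp4r2 (4.93 ± 0.34) in type A1. In preleptotene they lay on Arih1 (8.38 ± 0.75), Gsk3b (8.18 ± 0.74) and Relch (8.04 ± 0.18). Kpna4 (8.57 ± 0.19), Cmtm2a (8.47 ± 0.66) and H3f3b (8.23 ± 0.17) led in pachytene/diplotene, and Cmtm2a (5.66 ± 0.32), Atxn1l (5.15 ± 0.40) and Ccnyl1 (5.09 ± 0.32) in round spermatids.

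Genes marked in 1 stage alone numbered 1045 in undifferentiated spermatogonia, 250 in type A1, 262 in preleptotene, 449 in pachytene/diplotene and 688 in round spermatids. All pairs of stages but 1, consecutive or not, shared more genes than independent lists of the same lengths would, drawn from the 11972 genes marked in any stage. Pachytene/diplotene and round spermatids shared 4388 genes where independent lists would share 3147, type A1 and preleptotene shared 6090 where 4564 would be, and undifferentiated spermatogonia and preleptotene, which are not consecutive, shared 6775 where 5668 would be. Undifferentiated spermatogonia and round spermatids shared 3950, where independent lists would share 4261. That number depends on the 11972 genes as the pool and would be smaller in a larger one. Across shared genes, which are not independent replicates, Spearman's rho of the strongest peak was highest between undifferentiated spermatogonia and preleptotene (0.770) and lowest between type A1 and pachytene/diplotene (0.523).

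Gene lists differed in the stages where their members were marked. Among 103 spermiogenesis genes marked in any stage, 32, 27 and 35 were marked in undifferentiated spermatogonia, type A1 and preleptotene, against 84 in pachytene/diplotene and 86 in round spermatids. Genes of undifferentiated spermatogonia ran the opposite course, with 36, 22, 13, 3 and 1 of 37 marked along the 5 stages. Genes of the meiotic chromosome axis and recombination peaked at preleptotene, where 66 of 69 (95.7%) were marked. Each list was compared with all other genes marked in any stage by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 75 list and stage combinations, of which 32 lay above and 23 below the other genes. Several lists are named for a stage, and a transcript must be present to give a peak. Transcript levels and lengths were not analysed here, so these tests do not tell a list's methylation from its expression. Of all 64 list results called, transitions included, 18 held under every alternative run, which were 8 each except 3 for blood and macrophage markers in preleptotene and pachytene/diplotene. The alternative backgrounds do not enter the test of gains and losses, so they could not end a transition's call. The blood and macrophage markers entered the pool only through the undifferentiated table, which fixed their absence in later stages in advance. Their calls are therefore no support.

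**Figure D1:**
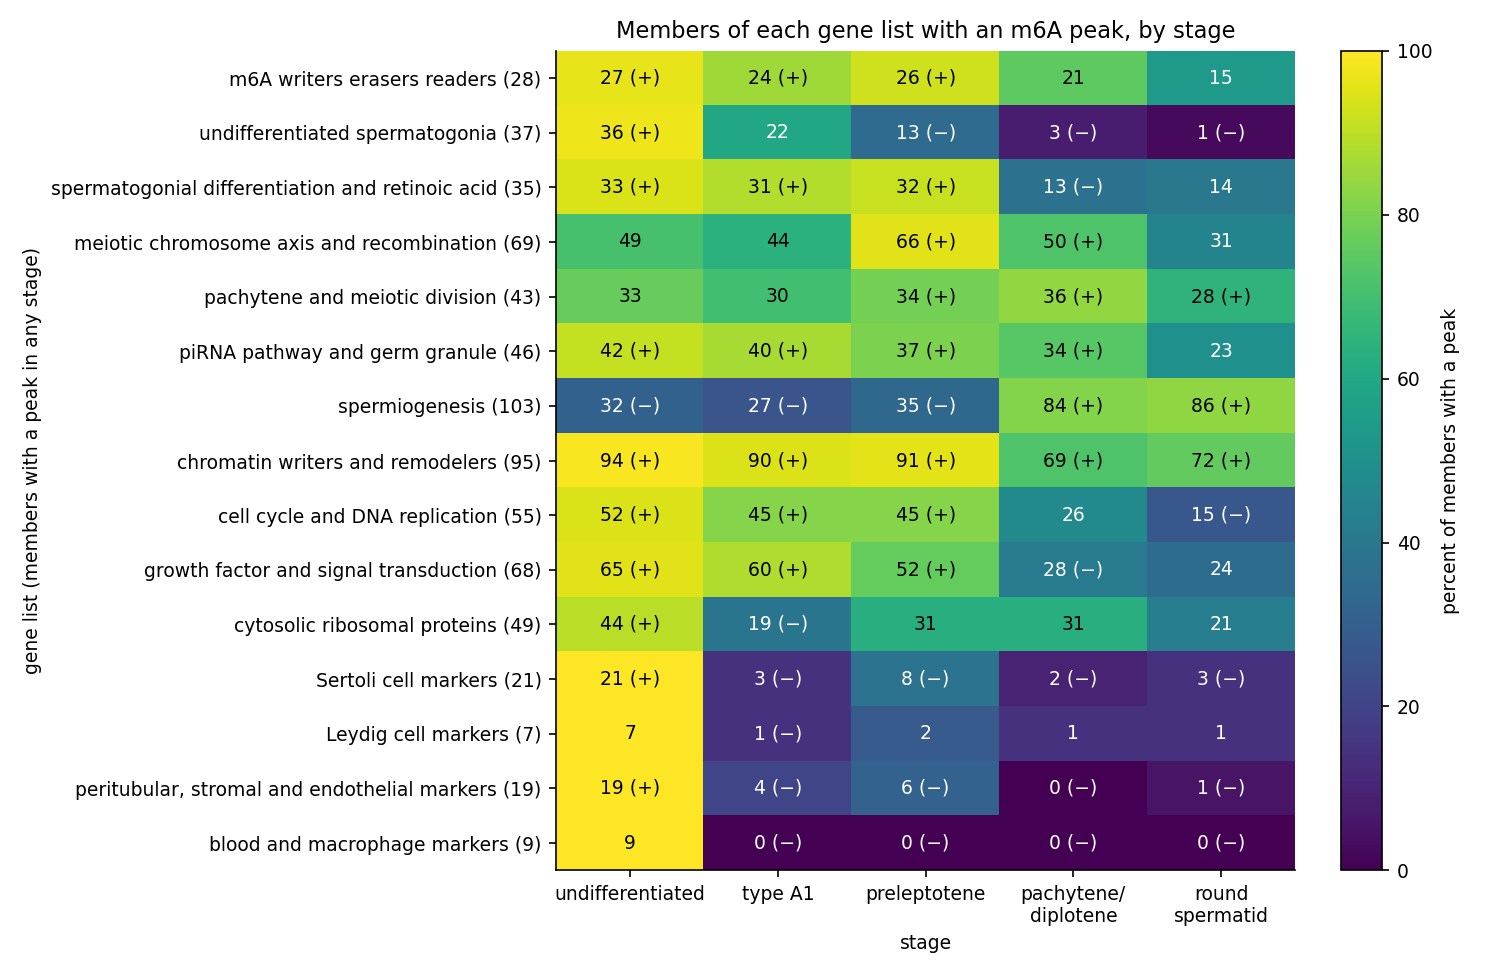
Number of members of each of 15 gene lists with a peak in each stage (numbers in cells) and the percent of the list's members marked in any stage (colour, 0 to 100%), with (+) and (−) for lists above or below the other marked genes at adjusted p under 0.05 by Fisher's exact test. Spermiogenesis genes go from 32 of 103 in undifferentiated spermatogonia to 86 of 103 in round spermatids, and undifferentiated spermatogonia genes from 36 of 37 to 1 of 37.

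Spermiogenesis genes lay below the other genes in the first 3 stages (31.1% against 76.3%, adjusted p = 4.51e-20, in undifferentiated spermatogonia) and above them in the last 2 (81.6% against 55.9%, adjusted p = 4.02e-07, and 83.5% against 46.6%, adjusted p = 4.72e-13). All 5 calls held under each of the 8 alternative settings tried. Dpy19l2, needed for attachment of the acrosome to the nucleus, was strongest in pachytene/diplotene (7.75 ± 0.10) and in round spermatids (4.91 ± 0.26). Hydin, a gene of the ciliary central apparatus, followed in round spermatids at 4.45 ± 0.44, with Acrbp at 3.80 ± 0.39 and Spag6l at 3.68 ± 0.13. The protamine gene Prm1 (chromosome 16, 10796332 to 10796823, mm10) carried 1 peak in pachytene/diplotene (2.69 ± 0.16) and 1 in round spermatids (2.27 ± 0.37), and the transition protein gene Tnp1 had no peak in any table. Crem, which encodes a transcriptional activator of spermatid genes, was marked at the stop codon in undifferentiated spermatogonia (3.04 ± 0.33) and pachytene/diplotene (3.12 ± 0.05) and had no peak in round spermatids.

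Undifferentiated spermatogonia genes were marked at 97.3% in the undifferentiated table (adjusted p = 0.00199), 35.1% in preleptotene (adjusted p = 0.00244), 8.11% in pachytene/diplotene (adjusted p = 1.38e-08) and 2.70% in round spermatids (adjusted p = 2.31e-08). Of 8 alternatives, 2 ended the first of these calls, 3 the second and 0 the last 2. The strongest in undifferentiated spermatogonia were Gfra1, the GDNF co-receptor (6.06 ± 0.90), the transcription factor gene Bcl6b (5.71 ± 0.27), Sdc4 (5.48 ± 0.13) and the Polycomb gene Bmi1 (5.43 ± 0.62). Bmi1 was the only member still marked in round spermatids (1.89 ± 0.24). The undifferentiated table also held 56 of 88 markers of Sertoli, Leydig, peritubular, endothelial, blood and macrophage cells, against 8, 16, 3 and 5 in the 4 later stages. Among these were Sox9 (5.30 ± 0.49), Kitl (5.02 ± 0.48), Pdgfra (5.90 ± 0.15), Hsd3b1 (3.79 ± 1.15), C1qc (5.02 ± 0.64) and Csf1r (3.58 ± 0.07). Sertoli markers were all marked there (21 of 21, adjusted p = 0.00856), as were peritubular, stromal and endothelial markers (19 of 19, adjusted p = 0.0204), calls lost under 3 and 5 of 8 alternatives. Leydig markers (7 of 7, adjusted p = 0.251) and blood and macrophage markers (9 of 9, adjusted p = 0.157) did not pass there. The blood and macrophage markers are in the tested pool only through this table, so 9 of 9 was fixed in advance. Some members of the other somatic lists are also in the pool only through it. The full marking of those lists there was therefore partly fixed. In type A1, 59.5% of undifferentiated spermatogonia genes were marked against 61.1% of other genes (adjusted p = 0.890). With genes marked only in the undifferentiated table left out of the comparison, a choice made after seeing the data, the list lay 24.8 points above the other genes there (adjusted p = 0.0177).

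Meiotic axis and recombination genes were not set apart in the 2 spermatogonial stages, with 71.0% (adjusted p = 0.376) and 63.8% (adjusted p = 0.762) marked. They lay above the other genes in preleptotene (95.7% against 62.2%, adjusted p = 1.43e-09) and pachytene/diplotene (72.5% against 56.0%, adjusted p = 0.0128). The second of these calls was lost under 6 of 8 alternatives. Atm, the DNA damage kinase gene (6.01 ± 0.29), Meioc, a regulator of meiotic entry (5.90 ± 0.57), and Sycp1, encoding the synaptonemal complex transverse filament (5.87 ± 0.58), led in preleptotene. Sycp1 and Sycp3 were marked in all 5 stages, Sycp3 with a single peak each time, at the start codon in the 4 tables that label it (4.87 ± 0.11 in undifferentiated spermatogonia and 2.00 ± 0.04 in round spermatids). Genes of pachytene and meiotic division lay above the others in pachytene/diplotene (36 of 43, adjusted p = 0.000585, lost under 3 of 8 alternatives), led by the transcription factor gene Mybl1 (7.19 ± 0.29) and the RNA-binding gene Boll (5.48 ± 0.68). They also did so in preleptotene (adjusted p = 0.0364, lost under 7 of 8 alternatives) and round spermatids (adjusted p = 0.0300, lost under 6 of 8). Genes of the piRNA pathway lay above the others in the first 4 stages, with 42, 40, 37 and 34 of 46 marked and adjusted p of 0.0227, 0.000659, 0.0227 and 0.0250. At least 4 of 8 alternatives ended each of those calls.

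Genes of spermatogonial differentiation and retinoic acid response were marked above the others in the first 3 stages (33, 31 and 32 of 35, adjusted p = 0.0153, 0.00186 and 0.000585) and below them in pachytene/diplotene (13 of 35, adjusted p = 0.0364). Of 8 alternatives, 4, 4, 4 and 2 ended these calls. Dmrt1, a transcription factor gene of the mitosis to meiosis switch, stood at 7.66 ± 0.60 in undifferentiated spermatogonia and 6.15 ± 0.29 in preleptotene. Chromatin writers and remodelers lay above the others in all 5 stages, with 94, 90, 91, 69 and 72 of 95 marked (adjusted p from 4.72e-13 in preleptotene to 0.00286 in pachytene/diplotene, the latter lost under 1 of 8 alternatives and the other 4 kept under all). Suz12, a Polycomb subunit gene, stood at 7.28 ± 0.42 in undifferentiated spermatogonia, 4.72 ± 0.05 in type A1 and 3.45 ± 0.22 in round spermatids, and Smarca5 led in pachytene/diplotene at 6.54 ± 0.14. Cell cycle and DNA replication genes went from 52 of 55 marked in undifferentiated spermatogonia (adjusted p = 0.00126) to 15 of 55 in round spermatids, below the others (adjusted p = 0.00847). Of 8 alternatives, 3 ended the first call and 1 the second. Growth factor and signalling genes were above the others in the first 3 stages (65, 60 and 52 of 68) and below them in pachytene/diplotene (28 of 68, adjusted p = 0.0227), with 1, 0, 4 and 2 of 8 alternatives ending the calls. Cytosolic ribosomal protein genes were above in undifferentiated spermatogonia (44 of 49, adjusted p = 0.0281) and below in type A1 (19 of 49, adjusted p = 0.00410), calls lost under 5 and 1 of 8 alternatives. With the same number of best peaks from every table, the undifferentiated value for ribosomal protein genes turned to 18.8 points below the others, a difference of -18.8 (adjusted p = 0.0879).

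The m6A machinery itself was marked, with 27, 24, 26, 21 and 15 of 28 genes of writers, erasers and readers along the 5 stages. The list lay above the other genes in the first 3 stages (adjusted p = 0.0128, 0.0120 and 0.00164, lost under 4, 4 and 2 of 8 alternatives) and was not set apart in the last 2 (adjusted p = 0.0727 and 0.629). The demethylase gene Alkbh5 (chromosome 11, 60537683 to 60558512) was the strongest member in every stage but type A1, at 7.79 ± 1.03 in undifferentiated spermatogonia, 7.43 ± 0.75 in preleptotene, 6.43 ± 0.11 in pachytene/diplotene and 3.67 ± 0.73 in round spermatids. Mettl14, encoding the RNA-binding partner of the methyltransferase, was marked in 4 stages and had no peak in round spermatids. Its strongest peak lay at the start codon in undifferentiated spermatogonia (4.97 ± 0.38) and in pachytene/diplotene (3.93 ± 0.57). Mettl3, the catalytic subunit gene, was marked in undifferentiated spermatogonia (2.36 ± 0.61) and preleptotene (2.16 ± 0.54) only. Ythdf2 and Fto were marked in all 5 stages. Ythdc2, a reader gene required for meiotic progression, was marked in type A1 (1.44 ± 0.06), preleptotene (3.28 ± 0.79, 6 peaks) and pachytene/diplotene (2.24 ± 0.92). Its type A1 value lies below the lowest listed undifferentiated peak (1.48). Undifferentiated values at its preleptotene peaks reached 1.55 without being listed. Its mark in type A1 but not in undifferentiated spermatogonia is therefore not shown to be a difference.

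The next comparisons ask which transcripts gained or lost m6A between consecutive stages. A gene with a peak in the earlier stage only is called lost and one with a peak in the later stage only gained. No replicate error attaches to a gain or loss, since each stage has 1 list, and transcript levels were not analysed here, so a gene without a peak is not shown to be unmethylated. The lists also differ in their lowest listed enrichment, so a weak peak can count as gained or lost through the lists alone. List members gained and lost were set against those of all other genes by Fisher's exact test (two-sided), adjusted over 50 list and transition combinations, of which 2 were called gained and 7 lost. Of the 8 alternatives cited for a gain or loss call, the 2 other backgrounds do not enter this test and leave it unchanged. Where a table holds both stages' values at its peaks, single peaks were tested with limma, 2 replicates against 2, after centring each replicate's values on their median over all peaks. Higher and lower are then relative to these medians. Centring does not remove a difference in spread. At type A1 peaks the SD across peaks was 0.68 and 0.66 in type A1 against 1.21 and 1.14 in preleptotene. At round spermatid peaks it was 0.69 and 0.70 against 1.25 and 1.22 in pachytene/diplotene. The gap was smaller in the other comparisons. Through spread alone a strong peak can come out lower in the narrower stage, and a weak one higher. Quantile normalization, an alternative below, evens the spread. Only peaks listed for the stage named first were tested, a selection that by itself favours higher values in that stage. With peaks common to both stages only, the excess of higher peaks shrank in every comparison. It reversed for type A1 against preleptotene (796 higher, 1181 lower) and round spermatids against pachytene/diplotene (255 higher, 487 lower).

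**Figure D2:**
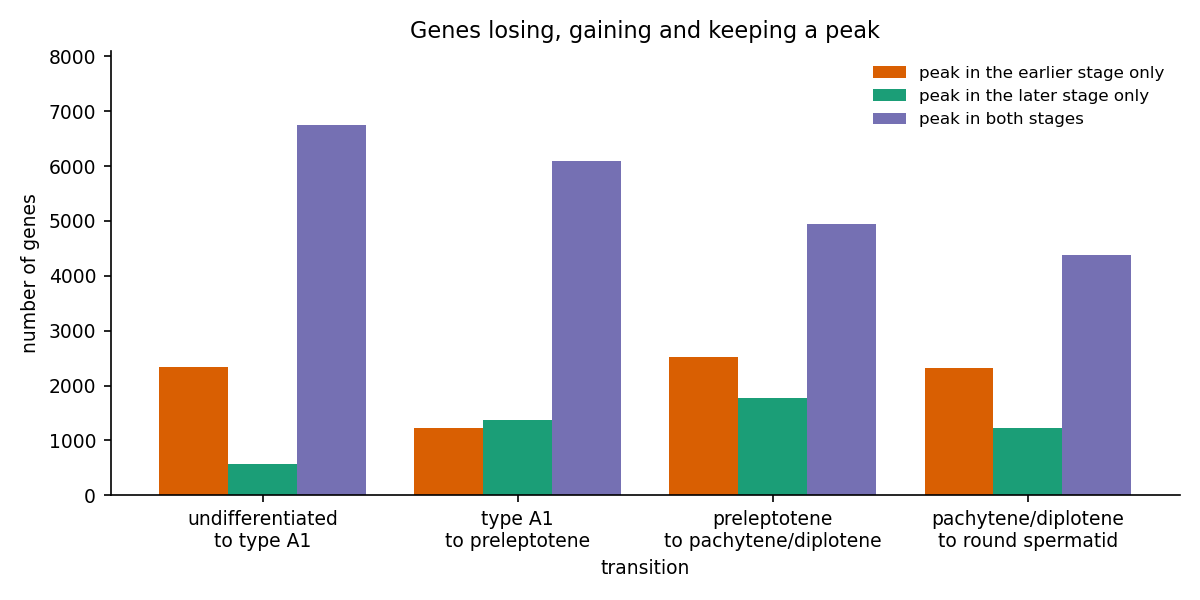
Number of genes (vertical axis) with a peak in the earlier stage only, the later stage only or both stages, at each of the 4 transitions. Losses outnumber gains most from undifferentiated to type A1 spermatogonia (2337 against 566), and in these full lists gains exceed losses from type A1 to preleptotene (1377 against 1227).

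From undifferentiated to type A1 spermatogonia, 2337 of 9088 marked genes (25.7%, Wilson 95% interval 24.8 to 26.6%) lost their peaks, 566 gained one and 6751 kept one. The type A1 libraries, on the later side of this step, had the lowest mapping rates (68.3% to 87.5%). With peaks of at least 4-fold enrichment 5367 genes were lost and 229 gained, and gains numbered 1376 with the same number of best peaks. The strongest losses were Pmaip1, a pro-apoptotic Bcl-2 family gene (7.38 ± 0.27), Ggnbp2 (6.54 ± 0.14), Marcks (6.34 ± 0.19), Chmp1b (6.27 ± 0.63) and Eif3j1 (6.25 ± 0.26). The strongest gains were Faxc (3.89 ± 0.30), Med12l (3.46 ± 0.36), Nova1 (3.35 ± 0.05), Gcnt1 (3.22 ± 0.22) and Lonrf2 (3.21 ± 0.23). Of undifferentiated spermatogonia genes, 15 were lost, among them Spry4 (5.34 ± 0.08), Lhx1 (4.96 ± 0.16), Dusp6 (4.62 ± 0.53) and Thy1 (3.51 ± 0.28), and Fgfr3 was gained (1.85 ± 0.16). That ratio did not differ from the one of other genes (adjusted p = 0.496). The table's somatic markers went with these losses, since 18 Sertoli markers and 9 blood and macrophage markers were lost and none was gained (adjusted p = 0.122 and 0.441). Ribosomal protein genes had 29 losses, led by Rps13 (3.67 ± 0.31) and Rpl27a (3.50 ± 0.87), and 4 gains (adjusted p = 0.540). Prdm9, which sets meiotic recombination sites, was among the meiotic genes gained (2.30 ± 0.06).

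At single sites, 3634 of 22843 peaks of undifferentiated spermatogonia were higher than at the same place in type A1 and 2107 were lower (limma, adjusted p under 0.05). The higher peaks were led by the coding peak of Hnrnpa0, an RNA-binding protein gene (chromosome 13, 58125879 to 58128556), at 8.61 ± 0.01 against 1.52 ± 0.32, a centred difference of 5.41 (SE 0.29, adjusted p = 0.000208). The start codon peak of Hmgn1, a nucleosome-binding protein gene, differed by 5.31 (SE 0.26, adjusted p = 0.000208), followed by Srsf6 (4.62), the cyclin gene Ccna2 (4.52) and Actr3 (4.33). The lower peaks were led by the zinc transporter gene Slc30a4 at -3.13 (2.02 ± 0.57 against 3.46 ± 0.02, adjusted p = 0.00183), followed by Trappc13 (-2.71), Rfk (-2.66), Arrdc2 (-2.61) and Fam126b (-2.56). Gfra1 was higher at its 5' UTR peak (6.06 ± 0.90 against 1.29 ± 0.18, centred difference 3.09, adjusted p = 0.00097) and at its start codon (1.71). Also higher were Alkbh5 (3.16 at the start codon), Mettl14 (2.16), Sycp1 (2.16 at the start codon, adjusted p = 0.00924), Dazl (1.96) and Zbtb16 (1.06). Kit, the receptor gene of differentiating spermatogonia, was lower at its 3' UTR peak by a centred difference of -1.13 (adjusted p = 0.0414), and Ythdf2 was higher at its start codon (1.14, adjusted p = 0.0133) and lower at a coding peak (-0.85, adjusted p = 0.0450). Without centring the Kit and the coding Ythdf2 differences were above 0 (0.55 and 0.84). With quantile normalization the Actr3 difference was 2.82 and that of the Alkbh5 start codon 2.06.

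Of 21 Sertoli marker genes, 14 had a higher peak and 1 a lower one, with 23 peaks called over all peaks and 26 when adjusted over the list alone. The list was called up by camera with a preset correlation (median difference 0.84, adjusted p = 0.0175), with adjusted p = 0.843 with an estimated correlation and 0.0497 by fry. Of 32 undifferentiated spermatogonia genes tested, 12 had a higher peak only, 3 a lower one only and 6 both. For that list 39 peaks were called, and 47 when adjusted over the list alone. Camera did not call it (adjusted p = 0.383, and 0.843 with an estimated correlation), and fry did (adjusted p = 0.0433). Chromatin genes had 35 members with higher peaks only and 16 with lower only of 94, and growth factor and signalling genes 21 and 20 of 65. For growth factor, meiotic and piRNA pathway genes the median difference was above 0 (0.09, 0.04 and 0.05) while camera's direction was down, none of them called. Camera sets a list against the other genes, and over all genes the centred difference had a median of 0.10 and a mean of 0.14. Centring took off 1.69, and the median of the differences was 1.79 before it and 0.10 after. Without centring 20638 peaks were higher and 9 lower. The split was 4883 to 1374 when centred on the peaks common to both stages and 2554 to 2498 with quantile normalization. It was 1398 to 400 without type A1 replicate 1, 2113 to 971 without type A1 replicate 2, and the lower peaks numbered 3467 without undifferentiated replicate 2.

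From type A1 spermatogonia to preleptotene spermatocytes, 1377 genes gained a peak, 1227 lost theirs and 6090 kept one. The type A1 libraries, with the lowest mapping rates (68.3% to 87.5%), are on the earlier side here. Somatic markers with a peak went from 8 to 16 of 88, and Sertoli markers had 5 gains and no loss (adjusted p = 0.169). With peaks of at least 4-fold enrichment 4045 were gained and 524 lost, and with the same number of best peaks losses exceeded gains. Meiotic axis and recombination genes had 24 gains and 2 losses, 92.3% gains against 52.5% among other genes (adjusted p = 0.000478). Gains included Meioc (5.90 ± 0.57), the crossover genes Msh4 (4.99 ± 0.51) and Msh5 (4.52 ± 0.11), and Terb2, which attaches telomeres to the nuclear envelope (4.68 ± 0.33). The 2 losses were Helb (2.12 ± 0.26) and H2ax (1.58 ± 0.33). The call was lost under 3 of 8 alternatives, with adjusted p up to 0.192. Meioc and Msh5 already had a peak in undifferentiated spermatogonia (2.75 ± 0.23 and 3.23 ± 0.48). A gain from type A1 is therefore not always a first mark. Undifferentiated spermatogonia genes had 10 losses and 1 gain (adjusted p = 0.0302, lost under 4 of 8 alternatives). Lost members included Bcl6b (2.66 ± 0.11), Etv5 (2.62 ± 0.34), Erbb3 (2.24 ± 0.35) and Gfra1 (2.19 ± 0.10), and Sox3 was gained (3.13 ± 0.85). Growth factor and signalling genes had 9 losses, with Notch1 (3.47 ± 0.12), Smad7 (3.08 ± 0.20), Tead1 (2.68 ± 0.20) and Acvr1 (2.49 ± 0.29) strongest, and 1 gain, Braf (3.65 ± 0.06), at adjusted p = 0.0455 (lost under 5 of 8 alternatives).

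Among other lists at this step, spermiogenesis genes had 12 gains and 4 losses (adjusted p = 0.199), with Acrbp at 4.07 ± 0.42 and Crem at 3.48 ± 1.24. Ribosomal protein genes had 17 gains and 5 losses (adjusted p = 0.122), and Mybl1 was gained at 5.42 ± 0.49. The m6A machinery gained Zcchc4 (3.65 ± 0.23), Mettl5 (3.64 ± 0.38), Hnrnpa2b1 (3.09 ± 0.32) and Mettl3, and lost Cbll1 and Igf2bp2 (adjusted p = 0.822). Zcchc4, Mettl5, Hnrnpa2b1 and Mettl3 had also been marked in undifferentiated spermatogonia (3.52 ± 0.24, 4.09 ± 0.88, 4.03 ± 0.38 and 2.36 ± 0.61). So had Acrbp (4.70 ± 0.13), Crem (3.04 ± 0.33) and Mybl1 (2.53 ± 0.13). Over all genes the strongest gains were Slc26a8, a sperm anion transporter gene (6.40 ± 0.40), Itfg1 (6.20 ± 1.25), Hectd2 (6.15 ± 0.24), Meioc and Laptm4b (5.87 ± 0.18). The strongest losses were Faxc (3.89 ± 0.30), Il13ra1 (3.80 ± 0.39), Camk4 (3.67 ± 0.15), Abcg1 (3.65 ± 0.43) and Lgalsl (3.65 ± 0.26).

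Of 16309 type A1 peaks tested, 2353 were higher in type A1 than in preleptotene and 2212 lower (limma). Lpcat1 (centred difference 4.26), Mpped1 (4.12), the glycosyltransferase gene Gcnt1 (3.60), Prtg (3.53) and Ugcg (3.53) led the higher peaks. Lonrf3 (-4.18, 2.31 ± 0.24 against 7.55 ± 0.38), the small GTPase gene Rab14 (-4.10), Pole4 (-3.79), Taok1 (-3.76) and Ube2d3 (-3.69) led the lower ones, all 10 at adjusted p of 0.00215 or less. Undifferentiated spermatogonia genes had a higher type A1 peak in 14 of 21 members and a lower one in 2, with 24 peaks called and 32 when adjusted over the list alone. All 3 Gfra1 peaks called lay in the 3' UTR (centred differences 1.93 to 2.41). The list was called up by camera (median difference 0.87, adjusted p = 0.0175), with adjusted p = 0.843 with an estimated correlation and 0.0220 by fry. Meiotic genes had lower peaks only in 14 of 44 members, higher only in 3 and both in 3, with 30 peaks called and 29 when adjusted over the list alone. They were called down by camera (median difference -0.24, adjusted p = 0.0481), but not with an estimated correlation (adjusted p = 0.843) or by fry (adjusted p = 0.187). Sycp1 was lower at its start codon (-2.69, adjusted p = 0.00741). Alkbh5 was lower at 6 peaks (-1.40 to -3.37), Kit at its start codon (-1.89, or -1.20 with quantile normalization), Dazl (-2.14) and Mettl14 (-1.88). The stop codon peak of Alkbh5 was not called with quantile normalization (adjusted p = 0.0528), and 2 of its other differences shrank by over 1.5 times (to -1.58 in coding sequence and -2.08 at the start codon). Among the fixed genes with a higher peak were Fto in the 3' UTR (1.67, adjusted p = 0.00527, or 0.91 with quantile normalization), Zbtb16 at the stop codon (1.47, adjusted p = 0.00639) and Ythdf2 in coding sequence (1.24, adjusted p = 0.0114). The last 2 were not called with quantile normalization (adjusted p = 0.0795 and 0.391). The median of the differences before centring was -1.07. The split was 510 to 10777 without centring, 3661 to 1363 when centred on the common peaks and 796 to 1181 with common peaks only. Without type A1 replicate 1 or 2 it was 633 to 411 and 967 to 790, and without preleptotene replicate 1 or 2 it was 3792 to 3678 and 4264 to 4079.

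Preleptotene peaks were also deposited against undifferentiated spermatogonia, which spans the course from the stem cell compartment to meiotic entry. Of 18706 peaks, 1002 were higher in preleptotene and 458 lower (limma). The higher ones were led by BC051142 (4.44), the cytoplasmic polyadenylation gene Cpeb2 (4.43, 6.01 ± 0.02 against 1.58 ± 0.23, adjusted p = 0.000271), the nuclear receptor gene Pparg (4.17), the Cdk activator gene Spdya (4.07) and the adhesion molecule gene Alcam (3.92). The lower ones were led by Rcan3 (-4.14, adjusted p = 0.000326), Myadm (-3.29), Mrpl15 (-3.13), the Hedgehog receptor gene Ptch1 (-3.09) and Sbk1 (-3.02). Meiotic axis and recombination genes had a higher peak in 15 of 66 members and a lower one in 1, with 30 peaks called and 36 when adjusted over the list alone. The list was called up by camera (median difference 0.23, adjusted p = 0.00105), but not with an estimated correlation (adjusted p = 0.843) or by fry (adjusted p = 0.0891). The start codon peak of Sycp1 differed by -0.02 (limma, adjusted p = 0.984). Ythdc2 was higher at 3 coding peaks (2.17, 1.69 and 1.67), the last 2 of which were not called with quantile normalization (0.68 and 1.18, adjusted p = 0.313 and 0.0790). Spermiogenesis genes had a higher peak in 5 of 35 members and a lower one in 0 (camera adjusted p = 0.0634, and adjusted p = 0.843 with an estimated correlation; fry adjusted p = 0.0265). Growth factor genes (median difference -0.06, mean 0.04) and pachytene and division genes (-0.05 and 0.11) had an upward camera direction, neither called, at a median of -0.03 and a mean of 0.03 over all genes. The median of the differences of all peaks before centring was 0.01, and without centring 862 peaks were higher and 355 lower. With quantile normalization 534 were higher and 237 lower, and 756 of the 1460 calls were kept. With common peaks only the split was 260 to 240, and without preleptotene replicate 1 or 2 it was 625 to 275 and 458 to 168.

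From preleptotene to pachytene/diplotene spermatocytes, 2526 of 7467 marked genes (33.8%, Wilson 95% interval 32.8 to 34.9%) lost their peaks, 1772 gained one and 4941 kept one. Somatic markers with a peak went from 16 to 3 of 88 at this step, with 6 Sertoli markers lost and none gained (adjusted p = 0.135). Spermiogenesis genes had 51 gains and 2 losses, 96.2% gains against 40.5% among other genes (adjusted p = 3.86e-16). This call held under all 8 alternatives, though the 2 backgrounds among them could not change it. Gains were led by Dpy19l2 (7.75 ± 0.10), Hydin (5.92 ± 0.11), Spag6l (5.52 ± 0.38) and Tcp11 (4.77 ± 0.36), and the losses were Rfx3, a regulator of ciliary genes (3.74 ± 0.93), and Spag4 (2.36 ± 0.07). Differentiation and retinoic acid genes had 19 losses and no gain (adjusted p = 0.000721), among them Dmrt1 (6.15 ± 0.29), the retinol dehydrogenase gene Rdh10 (6.08 ± 0.53), Kit (5.48 ± 0.44) and Dnmt3a (5.32 ± 0.09). Stra8, the retinoic acid target needed for meiotic entry, stood at 2.97 ± 0.18 in preleptotene and had no peak in either later stage. It was already marked in undifferentiated spermatogonia (2.74 ± 0.72) and type A1 (1.74 ± 0.12). Growth factor and signalling genes had 24 losses and no gain (adjusted p = 7.70e-05, kept under all 8 alternatives with the same limit). They were led by Bmpr2 (5.83 ± 0.56), Kit, Tgfbr1 (5.12 ± 0.30) and Fzd3 (5.00 ± 0.83).

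Chromatin genes had 24 losses, led by Kdm6a (5.79 ± 0.11) and Kdm5c (5.39 ± 0.64), both X-linked, and 2 gains, Setd1b (4.05 ± 0.16) and Smarca2 (2.98 ± 0.28), at adjusted p = 0.00215. Cell cycle genes had 22 losses, led by Ccna2 (5.47 ± 1.35), Orc6 (5.03 ± 0.55), Rb1 (4.51 ± 0.01) and Mcm4 (4.44 ± 0.34), and 3 gains, E2f8, Rpa2 and Gmnn (adjusted p = 0.0168). Meiotic axis and recombination genes had 18 losses, led by Atm (6.01 ± 0.29), Mei1 (4.89 ± 0.31), Brca1 (4.74 ± 0.21) and Trip13 (4.69 ± 0.27), and 2 gains, H2ax (2.28 ± 1.32) and Syce3 (2.23 ± 0.50), at adjusted p = 0.0303. Pachytene and meiotic division genes had 9 gains and 7 losses (adjusted p = 0.496). Gains included the germ cell poly(A) polymerase gene Papolb (4.43 ± 0.05), Ovol1 (3.48 ± 0.65) and the glycolytic isozyme genes Ldhc (2.99 ± 0.58) and Pgk2 (2.92 ± 0.39). In the piRNA pathway, Piwil1, encoding the pachytene Piwi protein (4.11 ± 0.54), and Tdrd6 (3.86 ± 0.01) were gained and Tnrc6b (5.13 ± 0.32) and Nanos1 (4.72 ± 0.40) lost, with 6 gains and 9 losses (adjusted p = 1). Piwil1 had also carried a peak in undifferentiated spermatogonia (2.60 ± 0.03). Over all genes the strongest gains were Cmtm2a (8.47 ± 0.66), Dpy19l2, Ptchd3 (7.67 ± 0.48), Pde1c (6.79 ± 0.19) and Lrrc34 (6.52 ± 0.26). The strongest losses were Lonrf3 (7.78 ± 0.06), Taf9b (7.44 ± 0.28), Syap1 (7.25 ± 1.54), Rab5a (7.16 ± 0.85) and Foxn2 (7.15 ± 0.40), the first 3 X-linked. The calls for chromatin, differentiation and meiotic genes were each lost under 2 of 8 alternatives and that for cell cycle genes under 3. The deposited ratios do not set preleptotene against pachytene/diplotene, so single peaks were not tested at this step.

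From pachytene/diplotene spermatocytes to round spermatids, 2325 of 6713 marked genes (34.6%) lost their peaks, 1225 gained one and 4388 kept one. With peaks of at least 4-fold enrichment 4588 were lost and 386 gained, and with the same number of best peaks gains exceeded losses. The strongest losses were H3f3b, which encodes a replacement variant of histone H3 (8.23 ± 0.17), Tbc1d12 (7.32 ± 0.22), Krit1 (6.68 ± 0.56), Pole4 (6.66 ± 0.11) and Ggnbp2 (6.64 ± 0.19). The strongest gains were Cdc14a (4.60 ± 0.21), the X-linked cullin gene Cul4b (4.51 ± 0.42), Tmem63c (4.13 ± 0.30), Smpd2 (3.94 ± 0.03) and Slc14a2 (3.88 ± 0.15). With the full lists no gene list was called at this step. With the same number of best peaks from every table, spermiogenesis genes were called gained, and ribosomal protein genes turned to 41.0 points above the other genes (adjusted p = 0.0226). Meiotic genes had 22 losses, among them Topbp1 (5.64 ± 0.43) and Msh4 (4.84 ± 0.03), and 3 gains (adjusted p = 0.0887). Spermiogenesis genes had 16 gains, including the sperm calcium channel gene Catsper1 (3.02 ± 0.13) and Spata3 (2.47 ± 0.25), and 14 losses, including Iqcg (5.48 ± 0.45) and Gopc (5.46 ± 0.52), at adjusted p = 0.122. The m6A machinery had 7 losses, among them Mettl14 (3.93 ± 0.57), Elavl1 (3.44 ± 0.29), the writer complex gene Zc3h13 (3.42 ± 0.94) and the reader gene Ythdf1 (3.24 ± 1.18), and 1 gain, Igf2bp1 (2.00 ± 0.19), at adjusted p = 0.477.

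Of 15514 pachytene/diplotene peaks tested, 1096 were higher than in round spermatids and 266 lower (limma). H3f3b led the higher ones (8.23 ± 0.17 against 0.06 ± 0.04, centred difference 6.56, SE 0.28, adjusted p = 1.29e-05), followed by Rnf227 (3.99), Taf2 (3.87), Ptchd3 (3.85) and Ubtd2 (3.84). Slc38a9 (-3.28), Hacd2 (-2.88), Ttll7 (-2.85), the X-linked Vsig1 (-2.79) and Ube2h (-2.78) led the lower ones. Alkbh5 (1.75 at the start codon), Dazl (2.30) and Sycp1 (2.28) were higher in pachytene/diplotene. The Alkbh5 call was lost with quantile normalization (adjusted p = 0.151). Meiotic genes had a higher peak in 10 of 49 members and a lower one in 1 (17 peaks called, 22 when adjusted over the list alone), and spermiogenesis genes in 5 and 1 of 84. Neither list was called (camera adjusted p = 0.165 and 0.307, fry adjusted p = 0.0958 and 0.401). Without centring the split was 14533 to 6, where the median of the differences was 1.62, and with quantile normalization it was 698 to 309. With common peaks only 488 were higher, and centred on the common peaks 139 were lower. It was 505 to 101 without round spermatid replicate 1 and 717 to 176 without pachytene/diplotene replicate 2, and the lower peaks numbered 162 without pachytene/diplotene replicate 1.

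At 10810 round spermatid peaks, 1745 were higher in round spermatids and 1176 lower. Smpd2, a sphingomyelinase gene (4.75, adjusted p = 0.00031), the chloride channel gene Ano1 (4.28), the insulin receptor gene Insr (3.80), Apoo (3.77) and Cul4b (3.72) led the higher ones. Ptchd3 (-3.90), Slain2 (-3.84), Hnrnpa0 (-3.76), the noncoding RNA Norad (-3.76) and Taf2 (-3.59) led the lower ones. Lower peaks were found in 9 of 23 piRNA pathway genes and higher in 1 (20 peaks called, 24 when adjusted over the list alone), with Piwil1 at -0.82 (adjusted p = 0.0491). Sycp3 (-1.37) and Sycp1 (-2.51 at the start codon) were lower too. With quantile normalization Piwil1 and Sycp3 were not called (adjusted p = 0.120 and 0.0593), and the Taf2 difference was -2.35. Neither list was called by camera (adjusted p = 0.115 and 0.374 for piRNA and meiotic genes), and fry called the first (adjusted p = 0.0220, against camera's adjusted p = 0.843 with an estimated correlation). Without centring the split was 540 to 7457, where the median of the differences was -1.23. It was 1140 to 689 with quantile normalization, 2326 to 694 when centred on the common peaks, 255 to 487 with common peaks only, 707 to 217 without round spermatid replicate 1 and 777 to 349 without round spermatid replicate 2.

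**Figure D3:**
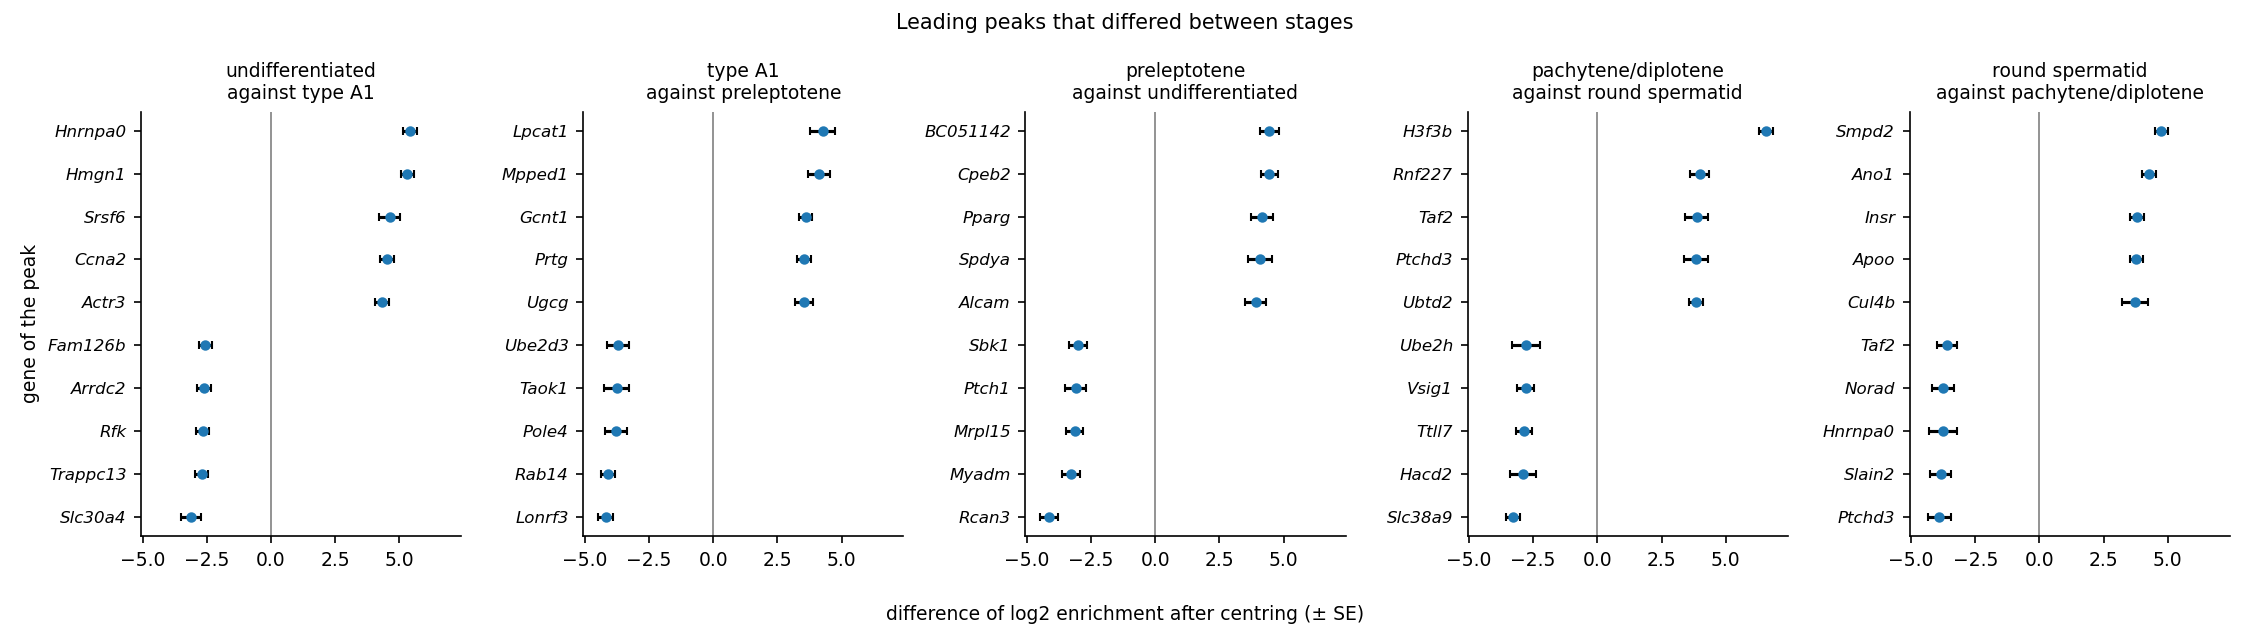
Difference of log2 enrichment between a stage and its comparison stage, with each replicate centred on its median over all peaks (horizontal axis, points with SE from limma, 2 replicates against 2), for the 5 highest and 5 lowest differences among peaks at adjusted p under 0.05 in each of 5 comparisons. The largest is the start codon peak of H3f3b, 6.56 higher in pachytene/diplotene than in round spermatids.

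Few X-linked genes were marked in pachytene/diplotene spermatocytes. Of 451 X-linked genes marked in any stage, 333, 253 and 282 were marked in the first 3 stages, 6 (1.33%) in pachytene/diplotene and 128 (28.4%) in round spermatids. In pachytene/diplotene 58.2% of genes on other chromosomes were marked. The 6 genes, named after their values were seen, were Car5b (3.95 ± 0.33), Chic1 (3.89 ± 0.69), Jpx, a noncoding activator of Xist (3.07 ± 0.25), Magt1 (3.05 ± 0.66), Vsig1 (2.84 ± 0.46) and Gm5643 (2.39 ± 0.39). Of 32 Y-linked genes marked in any stage, 12, 12, 15, 0 and 18 were marked along the 5 stages. The X-linked chromatin genes Kdm6a and Kdm5c were among those lost at this step, and Kdm5c was marked again in round spermatids (2.86 ± 0.01).

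**Figure D4:**
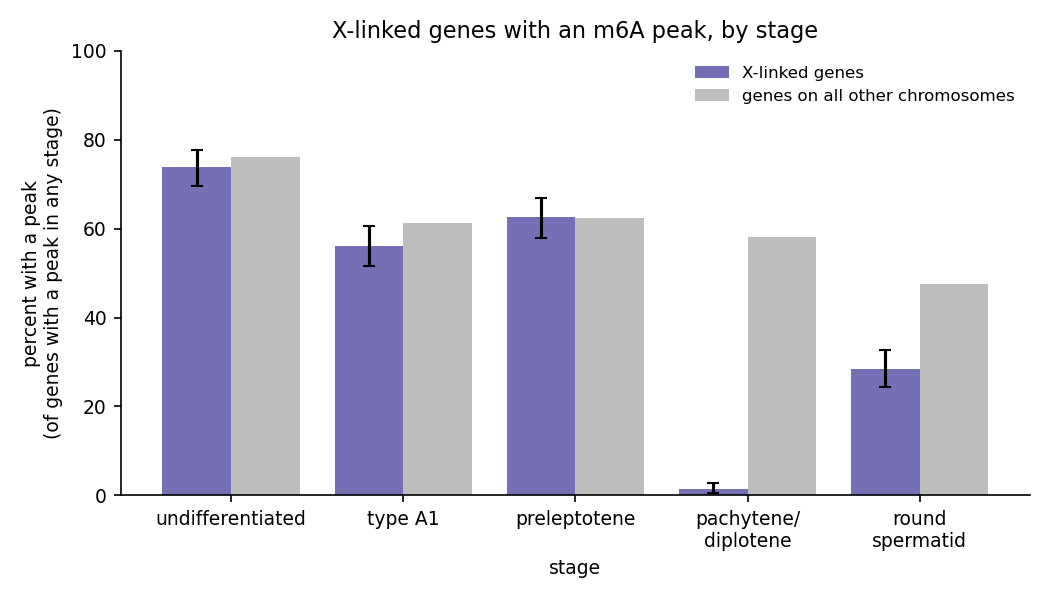
Percent of genes with a peak in each stage (vertical axis, of genes marked in any stage) for 451 X-linked genes, with Wilson 95% intervals for counting error, and for genes on all other chromosomes. X-linked genes are at 1.33% in pachytene/diplotene against 58.2% elsewhere and at 28.4% in round spermatids.

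Coding sequence held 59.9% of peaks in undifferentiated spermatogonia, 50.5% in type A1, 58.2% in preleptotene, 61.7% in pachytene/diplotene and 62.1% in round spermatids. In type A1 the share was 43.2% to 46.3% under the 3 stricter choices of peaks. Type A1 had the largest shares in the 3' UTR (19.4%, Wilson 95% interval 18.8 to 20.0%) and at the stop codon (14.8%, 14.2 to 15.3%). Its libraries also had the lowest mapping rates. The 3' UTR share was 13.0% in undifferentiated spermatogonia, 14.6% in preleptotene, 9.77% in pachytene/diplotene and 9.28% in round spermatids. Start codon peaks made up 11.4%, 10.5%, 8.40%, 11.7% and 10.3% along the 5 stages, where the preleptotene value is a lower bound, since 1095 of its 4120 unlabelled peaks could not be assigned from coding peaks of the same transcript. Peaks at start codons included those of Alkbh5, Mettl14, Kit, Dazl, Sycp1, Sycp3 and Prm1. The strongest Ythdf2 and Zbtb16 peaks lay in coding sequence, and the strongest type A1 peaks of Kit and Gfra1 in the 3' UTR. Wilson intervals here and above cover counting error only.

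**Figure D5:**
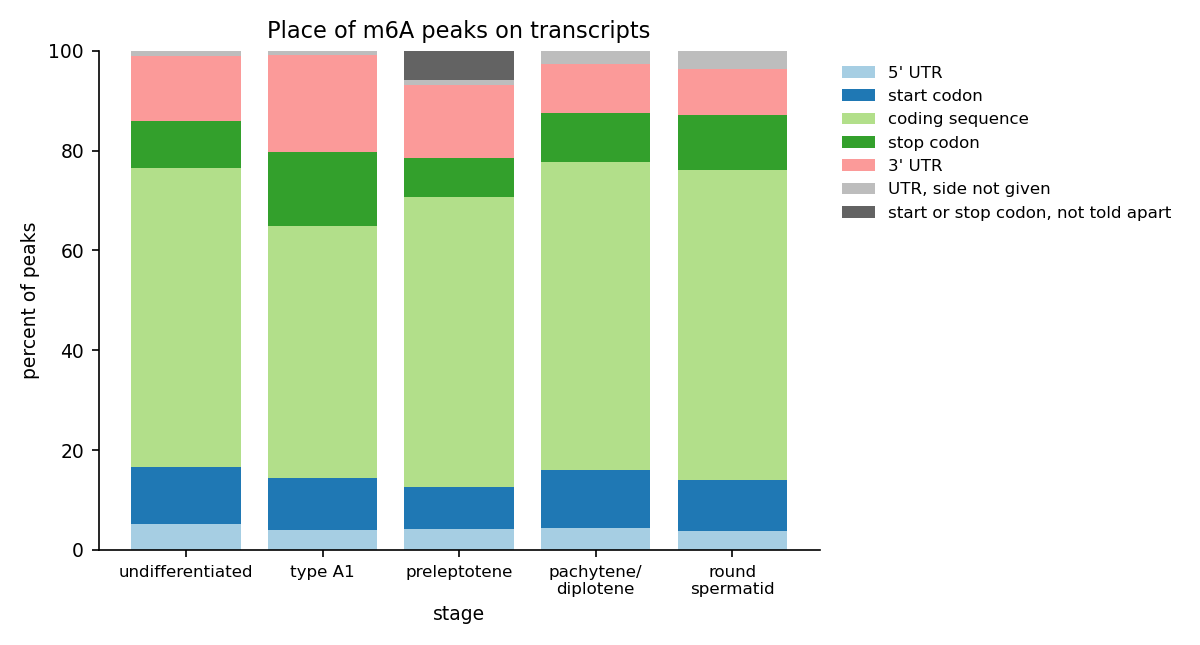
Percent of peaks (vertical axis) in each part of the transcript for the 5 stages, from the deposited location labels, with preleptotene start and stop codon peaks assigned from its blank labels. Type A1 has the lowest coding share (50.5%) and the highest 3' UTR share (19.4%), and 5.84% of preleptotene peaks could be placed at a start or stop codon without telling which.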

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

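All single-peak tests with limma and their alternatives (centring, quantile normalization, kept zeros, common peaks only, the replicate block and left-out replicates), the background without the undifferentiated table and the assignment of blank location labels were chosen after the data were seen, and the other alternatives before. Of 64 list results called, 18 held under every alternative. For gains and losses the alternative backgrounds do not enter the test and could not end a call. Among the 18 are calls for blood and macrophage markers, which the pool of tested genes fixed in advance. In all 141 of the alternative values moved, by more than 1.5 times for counts, and 158 stayed. The cause was not tested unless the setting itself reduces the peaks, genes or members counted.

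With peaks of at least 4-fold enrichment, fewer peaks remain by construction, most of all in the tables with low values. Peaks numbered 5974 (type A1) and 3482 (round spermatid) and genes 3859 (type A1) and 2407 (round spermatid), with 1226 genes marked in all 5 stages. Gains numbered 229 (undifferentiated to type A1), 4045 (type A1 to preleptotene) and 386 (pachytene/diplotene to round spermatid), losses 5367 (undifferentiated to type A1), 524 (type A1 to preleptotene) and 4588 (pachytene/diplotene to round spermatid) and kept genes 3630 (undifferentiated to type A1), 3335 (type A1 to preleptotene) and 2021 (pachytene/diplotene to round spermatid). Shared peaks numbered 5574 (undifferentiated to type A1), 4755 (type A1 to preleptotene) and 3042 (pachytene/diplotene to round spermatid). The 3' UTR share was 21.5 (type A1) and 10.2 (round spermatid) percent and the coding share 43.2 (type A1) and 57.8 (round spermatid) percent. Median log2 enrichment was 2.45 (type A1), 2.96 (preleptotene) and 2.44 (round spermatid).

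With the peaks above the median enrichment of each table, peaks numbered 11515 (undifferentiated), 8196 (type A1), 9374 (preleptotene), 7828 (pachytene/diplotene) and 5475 (round spermatid) and genes 4353 (pachytene/diplotene) and 3435 (round spermatid), with 1529 in all 5 stages. Gains numbered 879 (undifferentiated to type A1), kept genes 4004 (undifferentiated to type A1), 3666 (type A1 to preleptotene), 3051 (preleptotene to pachytene/diplotene) and 2542 (pachytene/diplotene to round spermatid) and shared peaks 5758 (undifferentiated to type A1), 5358 (type A1 to preleptotene), 4763 (preleptotene to pachytene/diplotene) and 3898 (pachytene/diplotene to round spermatid). The 3' UTR share was 12.1 (undifferentiated), 21.2 (type A1), 13.6 (preleptotene) and 10.5 (round spermatid) percent and the coding share 56.3 (undifferentiated), 44.9 (type A1), 54.1 (preleptotene), 58.2 (pachytene/diplotene) and 59.0 (round spermatid) percent. Median log2 enrichment was 3.73 (undifferentiated), 2.25 (type A1), 3.62 (preleptotene), 3.56 (pachytene/diplotene) and 2.15 (round spermatid). List and stage combinations called numbered 13 above and 12 below, and transitions called 2. The difference from other genes, in points, turned for cytosolic ribosomal proteins in preleptotene, at -36.7 (adjusted p = 0.0335) and piRNA pathway and germ granule in undifferentiated, at -1.71 (adjusted p = 0.886).

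With the same number of best peaks from every table, 10950 peaks remained in preleptotene and 10950 in undifferentiated spermatogonia. Gains numbered 1376 (undifferentiated to type A1) and shared peaks 6680 (undifferentiated to type A1), 7004 (type A1 to preleptotene) and 6132 (preleptotene to pachytene/diplotene). The 3' UTR share was 12.1 (undifferentiated) and 21.0 (type A1) percent and the coding share 55.9 (undifferentiated), 46.3 (type A1), 54.6 (preleptotene) and 59.8 (pachytene/diplotene) percent. Median log2 enrichment was 3.78 (undifferentiated), 2.06 (type A1), 3.47 (preleptotene) and 3.24 (pachytene/diplotene). Combinations below numbered 15. The difference turned for cytosolic ribosomal proteins in pachytene/diplotene to round spermatid, at 41.0 (adjusted p = 0.0226), cytosolic ribosomal proteins in preleptotene, at -33.1 (adjusted p = 0.00266), cytosolic ribosomal proteins in round spermatid, at 23.2 (adjusted p = 0.0348) and cytosolic ribosomal proteins in undifferentiated, at -18.8 (adjusted p = 0.0879).

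Counting only genes with at least 2 peaks, 1136 genes were marked in all 5 stages, gains numbered 673 (pachytene/diplotene to round spermatid) and kept genes 3587 (undifferentiated to type A1), 3262 (type A1 to preleptotene), 2660 (preleptotene to pachytene/diplotene) and 2051 (pachytene/diplotene to round spermatid). Combinations above numbered 15 and transitions called 5. The difference turned for cell cycle and DNA replication in preleptotene, at -2.47 (adjusted p = 0.782), cytosolic ribosomal proteins in undifferentiated, at -13.6 (adjusted p = 0.552) and spermatogonial differentiation and retinoic acid in preleptotene, at -0.211 (adjusted p = 1).

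Against a background of genes marked in at least 2 stages, 8 combinations lay above and 12 below, and the difference turned for Sertoli cell markers in preleptotene, at 22.4 (adjusted p = 0.321). Against a background without the undifferentiated table, 10 lay below, and it turned for Sertoli cell markers in preleptotene, at 31.7 (adjusted p = 0.0999), peritubular, stromal and endothelial markers in preleptotene, at 6.67 (adjusted p = 1) and undifferentiated spermatogonia in type A1, at 24.8 (adjusted p = 0.0177). Autosomal peaks only, members of 1 list only and a reciprocal overlap of 50% moved no summary count by over 1.5 times. Of list results, autosomal peaks only ended 2 calls and members of 1 list only ended 10.

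For single peaks tested with limma, counts outside 1.5 times the main ones were as follows. Without centring, higher peaks numbered 20638 (undifferentiated against type A1), 510 (type A1 against preleptotene), 14533 (pachytene/diplotene against round spermatid) and 540 (round spermatid against pachytene/diplotene) and lower peaks 9 (undifferentiated against type A1), 10777 (type A1 against preleptotene), 6 (pachytene/diplotene against round spermatid) and 7457 (round spermatid against pachytene/diplotene). Centred on the peaks common to both stages, higher peaks numbered 3661 (type A1 against preleptotene) and lower peaks 1374 (undifferentiated against type A1), 1363 (type A1 against preleptotene), 139 (pachytene/diplotene against round spermatid) and 694 (round spermatid against pachytene/diplotene). With common peaks only, higher peaks numbered 2153 (undifferentiated against type A1), 796 (type A1 against preleptotene), 260 (preleptotene against undifferentiated), 488 (pachytene/diplotene against round spermatid) and 255 (round spermatid against pachytene/diplotene) and lower peaks 1181 (type A1 against preleptotene), 240 (preleptotene against undifferentiated) and 487 (round spermatid against pachytene/diplotene). With quantile normalization, higher peaks numbered 534 (preleptotene against undifferentiated), 698 (pachytene/diplotene against round spermatid) and 1140 (round spermatid against pachytene/diplotene) and lower peaks 237 (preleptotene against undifferentiated) and 689 (round spermatid against pachytene/diplotene). Keeping exact zeros moved no count by that much.

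The replicate numbers do not pair the samples, since the deviations of same-numbered samples correlated at -0.13, -0.14, 0.12, 0.06 and 0.02 in the 5 comparisons. With the replicate number as a block, preleptotene against undifferentiated gave 1662 higher and 847 lower peaks, and no other count moved by over 1.5 times. With the numbers crossed, 4869 higher and 3044 lower peaks were called for undifferentiated against type A1 and 3040 and 2796 for type A1 against preleptotene.

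Leaving out each replicate in turn, where the lone sample left in a group is assumed to vary like the others, gave median log2 enrichments of 2.80 to 3.27 (undifferentiated), 1.73 to 1.78 (type A1), 2.92 to 2.94 (preleptotene), 2.64 to 3.13 (pachytene/diplotene) and 1.62 to 1.71 (round spermatid). Higher peaks ranged over 1398 to 5263 (undifferentiated against type A1), 633 to 4264 (type A1 against preleptotene), 458 to 976 (preleptotene against undifferentiated), 505 to 1175 (pachytene/diplotene against round spermatid) and 707 to 1921 (round spermatid against pachytene/diplotene) and lower peaks over 400 to 3467 (undifferentiated against type A1), 411 to 4079 (type A1 against preleptotene), 168 to 435 (preleptotene against undifferentiated), 101 to 218 (pachytene/diplotene against round spermatid) and 217 to 1295 (round spermatid against pachytene/diplotene). Where a count moved by over 1.5 times, the higher and lower peaks were, for undifferentiated against type A1 5263 and 3467 without undifferentiated replicate 2, 1398 and 400 without type A1 replicate 1 and 2113 and 971 without type A1 replicate 2. The same numbers were, for type A1 against preleptotene 633 and 411 without type A1 replicate 1, 967 and 790 without type A1 replicate 2, 3792 and 3678 without preleptotene replicate 1 and 4264 and 4079 without preleptotene replicate 2. The same numbers were, for preleptotene against undifferentiated 625 and 275 without preleptotene replicate 1 and 458 and 168 without preleptotene replicate 2. The same numbers were, for pachytene/diplotene against round spermatid 162 lower ones without pachytene/diplotene replicate 1, 717 and 176 without pachytene/diplotene replicate 2 and 505 and 101 without round spermatid replicate 1. The same numbers were, for round spermatid against pachytene/diplotene 707 and 217 without round spermatid replicate 1 and 777 and 349 without round spermatid replicate 2. Each stage has 1 list over both replicates, so peak and gene counts were not recomputed without a replicate.

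Matching on transcript length, the choice of transcript, peak centres and sequence motifs were not run, since no genome sequence or transcript model was used here. The pseudocount and count-model alternatives do not apply to log2 values. Depth behind single peaks is unknown, and its effect was not tested. With 2 samples against 2, the simulated recovery at a log2 difference of 1 was 0% to 4%. Far fewer peaks were changed there than were called in the data, so this is not the power of the tests on the data.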

Other observations

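The tests of a shorter peak list for X-linked genes and of the calling threshold at peaks of 1 stage were chosen after the results were seen, and the other 3 tests before.

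Markers of somatic testis cells were not absent after the undifferentiated stage. Sertoli markers lay below the other genes in the 4 later stages, with 3, 8, 2 and 3 of 21 marked (adjusted p = 6.82e-05, 0.0355, 7.82e-05 and 0.00713, Fisher's exact test) and these calls lost under 2, 5, 2 and 5 of 8 alternatives. Some of the 21 are in the tested pool only through the undifferentiated table, which by itself lowers the list's share in later stages. In preleptotene the direction turned to above under 2 other backgrounds, by 22.4 points with genes marked in at least 2 stages and 31.7 without the undifferentiated table (adjusted p = 0.321 and 0.0999). There Ctsl (4.93 ± 0.21), a lysosomal cathepsin gene that the fixed piRNA pathway list also holds without an evident reason, Aard (4.61 ± 0.66), Clu (4.46 ± 0.94) and the tight junction gene Cldn11 (4.37 ± 0.06) were the strongest of them. Peritubular, stromal and endothelial markers numbered 4, 6, 0 and 1 of 19 in these stages, with Sparc at 4.61 ± 0.25 in preleptotene and 2.46 ± 0.25 in round spermatids. Scarb1, which encodes a lipoprotein receptor, was marked in its 3' UTR in all 5 stages (4.80 ± 1.39, 3.20 ± 0.08, 4.56 ± 0.29, 3.51 ± 0.19 and 2.96 ± 0.09). No blood or macrophage marker had a peak after the undifferentiated stage.

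Some regulators had their strongest peak in the same part of the transcript from stage to stage. The p53 regulators Mdm2 and Mdm4 led the cell cycle list in pachytene/diplotene (5.82 ± 0.39 and 5.24 ± 0.39) and in round spermatids (4.05 ± 0.60 and 2.88 ± 0.22), each time in coding sequence. The kinase gene Gsk3b had a 5' UTR peak of 8.22 ± 0.09 in undifferentiated spermatogonia, 3.94 ± 0.05 in type A1 and 8.18 ± 0.74 in preleptotene. Pik3ca, a lipid kinase gene, had its strongest peak at the stop codon in undifferentiated spermatogonia (6.64 ± 1.07), type A1 (3.96 ± 0.33), pachytene/diplotene (6.36 ± 0.90) and round spermatids (3.45 ± 0.28). Rpl4 and Rpl15 were the 2 strongest ribosomal protein genes in every stage, at 4.35 ± 0.07 and 3.87 ± 0.27 in undifferentiated spermatogonia and 2.06 ± 0.18 and 1.91 ± 0.13 in round spermatids.

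X-linked genes rarely carried a peak in pachytene/diplotene spermatocytes, with 6 of 451. A list of that stage that is shorter or stricter for all genes alike is argued against. Of autosomal genes marked in any stage, 58.4% (Wilson 95% interval 57.5 to 59.3%) were marked there, with the counts known when the test was chosen. This share does not bear on stricter calling at transcripts with few reads. Low read numbers from X-linked transcripts, which meiotic silencing of the sex chromosomes would give, are a candidate explanation. At round spermatid peaks absent from the pachytene/diplotene list, 44.2% of X-linked pachytene/diplotene values equalled a ratio of whole numbers of at most 10. Among autosomal values 17.0% did, with a tolerance of 0.0001 on the log2 scale in both. The ratio of these shares was 2.60 (bootstrap interval 2.29 to 2.96). Whether methylation itself also differed on these transcripts was not tested.

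Somatic cell markers carried a peak mostly in undifferentiated spermatogonia, with 56 of 88. A longer list of that stage is argued against as the whole cause, since with the same number of best peaks 33 were marked there and 13 in the next highest stage, a ratio of 2.54. Low transcription of these genes in the germ cells themselves is left open. Values equal to such ratios, by the same limit and tolerance, were few at marker peaks (2 of 276) and elsewhere (439 of 45786). The ratio of these shares was 0.756 (bootstrap interval 0 to 1.95). Somatic cells in that preparation may be the source, which no value here decides, and so may germ cell transcription of the same genes. How the cells were isolated is not given in the sources used here.

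Peaks listed as unique to a stage mostly had log2 enrichments above 0 in both replicates of the comparison stage, from 83.5% for undifferentiated spermatogonia to 96.9% for preleptotene. The calling threshold of the comparison stage is a possible explanation of the missing calls. Of 29428 unique peaks, 22.0% (21.5 to 22.4%) lay above the 5th percentile of the comparison stage's own peaks in both replicates, a share that leaves this open. At peaks unique to type A1 the median deposited value was 1.58 there and 1.79 in preleptotene. At those unique to round spermatids it was 1.51 there and 1.59 in pachytene/diplotene. In the other tables the comparison stage had the lower median (0.68 against 2.70, 1.85 against 2.49 and 0.77 against 2.60). The tables state no common normalization. The counts of gained and lost genes rest on the same lists, so they do not by themselves show a difference in enrichment.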
